A study of Mus musculus with 16 samples.

How the data were processed

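Gene expression and hashtag libraries were made from pools of cultured mouse bone marrow progenitors with a droplet-based kit that reads the 3′ ends of transcripts, per the labels' protocols. Each pool combined 1 sample of each condition, and replicates were kept in separate pools. Cell Ranger 7.2.0, R 4.2.2, Seurat 4.4.0 and the genome build GRCm39 are named in the submitters' processing notes. The feature list itself names no build or annotation, so whether its 32285 genes come from GRCm39 was not established. The gene annotation, the settings of cell calling, the way in which the libraries were combined and the treatment of doublets are not given in the sources used here.

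The deposited files used here hold names and sequences and no measured values. They are the barcode list and the feature list that accompany a filtered matrix, and a table of hashtag sequences. Counts per gene and cell were not analysed here. The tests planned before the data were examined for the Sf1 gene, for all genes, for gene lists and for cell type shares need such counts and were not run. A planned test of barcode sequences shared between suffixes needs at least a pair of suffixes, and the list has 1.

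Barcodes were split into their bases and their suffix, and distinct sequences were counted. Base shares were computed at each of the 16 positions, and for each of the 120 pairs of positions the share of barcodes was computed in which the later position held the commonest base for the base at the earlier position. Pairs of barcodes that differ at exactly 1 base were counted and set beside the number expected if bases were drawn at random with the observed shares, with an exact one-sided Poisson test. The expected numbers were checked on 5 simulated lists with a fixed seed. These lists were drawn under the same assumptions, so they checked the calculation and not the assumptions.

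Gene identifiers were looked up in a table of mouse gene identifiers and symbols after removing version numbers. Of 32285 identifiers, 32158 (99.6%) were found, 31436 with the same symbol and 722 with another. Symbols are given as the feature list has them. No genomic coordinates are given, because the build behind the feature list was not established. The rule for named genes, fixed before the data were examined, allowed only Sf1 and the hashtags where no counts were in use. The other genes named were picked afterwards from the fixed gene lists, as examples. These 13 lists covered stem cells, neutrophils, monocytes and macrophages, dendritic cells, mast cells and basophils, eosinophils, megakaryocytes, erythroid cells, lymphoid cells, the cell cycle, splicing factors, translation, and interferon and stress responses. The calculations used Python 3.11.15, numpy 2.4.6 and scipy 1.17.1.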

Results

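The study edited the 5′ untranslated region of Sf1 in mouse blood progenitors and profiled the cells by droplet single-cell RNA sequencing. Sf1 encodes splicing factor 1, a protein that binds the intron branch point early in spliceosome assembly. Bone marrow cells enriched for the surface receptor c-Kit, which marks haematopoietic stem and progenitor cells, were expanded in culture for 21 days in medium with stem cell factor and thrombopoietin. Each pool held cells of 3 conditions, of which the control cells were unedited. In the others, Cas9 was directed to remove nucleotides 51 to 100 or nucleotides 251 to 300 of the Sf1 5′ untranslated region. The share of cells that carried each deletion was not analysed here. The labels describe 4 mice with 2 gene expression libraries and 2 hashtag libraries per mouse, or 8 libraries of each kind. The protocol in the labels has each pool loaded into quadruplicate wells, and how these wells relate to the 2 libraries per mouse is not given in the sources used here. A hashtag is a short oligonucleotide carried by an antibody against the cell surface, and reading it assigns each cell of a pool to its condition.

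The design implies a comparison of each Sf1 deletion with control cells, with the mouse as the replicate. The files analysed here were a list of cell barcodes, a list of features and the table of hashtag sequences, and none of them holds a count. The level of Sf1, the genes that differ between conditions, the cell types present and their shares were therefore not analysed here, and no statement about the effect of either deletion can be drawn from these files. Sequencing depth per library and per cell is unknown for the same reason.

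The series came with a single barcode list, and whether it covers all of the libraries was not established. It held 73429 barcodes of a matrix that the authors named as filtered, each with a sequence of 16 bases. All of them carried the same suffix, and no barcode could be placed in a mouse, a library or a condition. The 73429 sequences were all distinct. A list in which equal barcodes from different libraries had been merged would also hold no repeats, so 73429 is the number of listed barcodes and may differ from the number of cells captured. This number is a single value for the list without replicates, and the number of cells behind each mouse or condition was not analysed here.

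The hashtag table named the conditions. It listed 3 tag sequences of 15 bases each, named for control cells, for the deletion of nucleotides 51 to 100 and for the deletion of nucleotides 251 to 300. Any 2 of the tags differed at 10 to 13 of the 15 bases. Each tag was entered under 2 feature types, with 3 entries as gene expression and 3 as antibody capture. The feature list carried the 3 tags as antibody capture features only, under the same condition names without the ending that marked the type in the hashtag table.

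The feature list held 32285 genes beside the 3 tags. Sf1 appeared once, under the identifier ENSMUSG00000024949. Of the 142 genes on the 13 lists fixed before the data were examined, 142 were present under exactly 1 identifier each. Among all 32245 distinct gene symbols of the feature list, 38 stood on more than 1 identifier, so a single identifier was the usual case. The lists held cell type markers and also genes of the cell cycle, splicing, translation, and interferon and stress responses. They included the stem cell genes Hlf, Mecom and Procr, the neutrophil granule genes Elane and Mpo, the mast cell protease gene Cpa3, the platelet factor gene Pf4 and the erythroid transcription factor gene Klf1. The 12 splicing factor genes of that set, among them Sf1, U2af1, U2af2, Sf3b1 and Srsf2, were also present. Presence in this list says that reads could be assigned to a gene, and carries no information on whether the gene was expressed.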

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

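The number of barcodes was 73429 when lines were counted, when distinct sequences were counted and when only sequences under 1 suffix were counted. The list has neither repeated sequences nor a second suffix, so these alternatives had nothing to remove and say nothing about stability. The number of hashtags was 3 in both the hashtag table and the feature list. Counting distinct symbols in place of identifiers, an alternative chosen after seeing the data, gave 32245 genes in place of 32285, since 38 symbols stand for more than 1 identifier. The alternatives planned for barcodes shared between suffixes, for genes changed between conditions and for cell type shares gave no value, because there is 1 suffix and no counts were analysed here. No paired analysis was possible because the files used here hold no value per mouse or condition. Depth is unknown.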

Other observations

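The tests in this part were chosen after the data were seen, and they describe the barcode list, not the cells. Each base made up between 22.8% and 28.4% of the barcodes at each of the 16 positions. The base at position 8, counted from the first base of the barcode, fixed the base at position 9 in 100% of the 73429 barcodes. Among the other position pairs, the commonest base at the later position, given the earlier one, covered at most 32.2% of barcodes. That value was for position 6 given position 1, where the commonest base at position 6 alone covered 28.1%. Some of these pairs were therefore not independent. All pairs within positions 1 to 7 exceeded the share of the later position alone, such as position 5 given position 4 (31.0% against 25.3%). Within positions 8 to 16 some pairs did so clearly, such as position 14 given position 13 (28.6% against 26.4%). For other pairs there the excess was small, such as position 14 given position 8 (26.5% against 26.4%). Positions 1 to 7 paired with positions 8 to 16 gave shares at or near that of the later position alone. An example is position 13 given position 1 (26.5% for both). An equal share does not show that such positions were independent, because the measure uses only the commonest base.

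Only 2 pairs of barcodes differed at exactly 1 base. Random drawing with the observed base shares and independent positions would give 30.92 such pairs (exact one-sided Poisson p = 1.9e-11), and 108.16 with position 9 fixed by position 8 (exact one-sided Poisson p = 6.3e-44). The list therefore held fewer pairs 1 base apart than random sequences with the same base shares, and no other distance was measured. Both expectations took the remaining positions as independent, which some of them were not. Barcodes are limited to the kit's permitted list, so freely drawn sequences were not a possible source. The p-values therefore carry no information about the cells or the experiment. The kit's list of permitted barcodes was not used here. Whether that list has the same link between positions 8 and 9 and the same spacing was therefore not tested. Any effect of cell calling or barcode correction was not tested either.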
